A study of Homo sapiens with 4 samples.

How the data were processed

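Total RNA of KYSE170 cells was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols, with 2 arrays of untreated cells and 2 of cells given EDHB at 50 µg/ml for 12 h. The deposited table held 1 linear intensity per probe set and array, made with RMA per the submitters' processing notes, with software and version not given in the sources used here. RMA subtracts background, makes the intensity distributions of the arrays equal and summarises the probes of a probe set, which compresses small levels and removes any global difference between arrays. Intensities ranged from 1.55 to 13393 and were turned into log2 values, with no pseudocount and no further normalisation. The number of arrays, 2 per group, limits the precision.

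The table had 54613 rows and 0 control probe sets. The replicate 2 columns had 1 empty cell each and stood in another row order than the replicate 1 columns. Their order matched a sheet in which each pair of arrays had been sorted on its own (probe sets at least 2-fold higher, then 2-fold lower, then the rest, each in ID order) and the sheets laid side by side before a sort by the replicate 1 IDs. Under this layout, 148 probe sets of the replicate 2 pair stood in the higher list and 45 in the lower list, and the other 54419 ran in ID order. The layout is an inference from the values and is recorded in no label. The identity of each replicate 2 value was recovered with a forward-backward alignment that keeps ID order within the lists and the rest and compares log2 levels of the untreated arrays only (Student's t density with scale 0.15 and 3 degrees of freedom). The EDHB arrays entered only through the 2-fold lists that define the layout.

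A row was kept at a posterior of at least 0.95. This held for 54467 probe sets (99.7%), and 146 were left out, 119 of them with 1 gene. Of the 193 values in the replicate 2 lists, 75 stayed without a probe set, and 17 of the 118 probe sets changed at least 2-fold within replicate 1 were not restored, so the most changed probe sets are under-represented. Some gene list members that did not pass, as in the hypoxia and ATF4 lists, had an unrestored probe set that was higher within replicate 1. The replicate 1 columns carry the right IDs by the following check. The 113 ribosomal protein probe sets had a median log2 level of 12.4 in untreated replicate 1, 6.61 in untreated replicate 2 as deposited and 12.4 there once restored. Checks on values the alignment did not compare gave a median absolute difference between the EDHB arrays of 0.113 log2 units (0.125 between untreated arrays). Matching on untreated levels favours a small difference here, since EDHB levels follow untreated ones. The correlation of log2 changes between the replicates across probe sets went from 0.04 to 0.38. Of the restored list members, 92 of 95 in the higher list and 20 of 23 in the lower list had the same sign within replicate 1. A replicate 2 with a known order was simulated with the noise and layout that the alignment assumes, so it does not test those assumptions. There, 54506 of 54613 rows were restored and 4 of these were wrong. Of 193 simulated list rows, 137 were restored and 2 of these were wrong.

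Probe sets were named through the platform annotation, with symbols checked through gene identifiers against a RefSeq table. Of the probe sets, 41091 had 1 gene, 1801 several and 11721 none listed. No symbol needed updating, and 54 probe sets kept the annotation's symbol because the identifier had no match. The array table names no genome build, and no coordinates are given. Each gene was represented by its brightest restored probe set among those with 1 gene, which left 19752 genes and no filter on dim genes. Where other restored probe sets of a named gene went the other way, their number is given, and it counts restored ones only. Of the genes named in the text, 8 had 10 probe sets that were not restored, and within replicate 1 all 10 had the sign of the one used. This leaves aside the fixed genes with no restored probe set. Genes below the median probe set (4.54) have levels not shown to be above background. With every probe set tested on its own, 0 were called, so at that level all probe sets of the named genes missed the threshold.

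EDHB was compared with untreated cells by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05, no block). The residual degrees of freedom were 2 and the prior ones 3.06. On simulated data of the 19752 genes with 200 changed, this test recovered 2% of genes changed by 0.5 log2 units, 82% at 1, 90% at 1.5 and 98% at 2, with 4 wrong calls. The intensity-trend fit recovered 24%, 86%, 90% and 98%, with 11 wrong calls. These simulations drew independent errors, with variances from the prior of the intensity-trend fit. In the data, the default fit called 2 of the 26 genes changed at least 2-fold within both replicates, so the simulated shares do not carry over to them. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the restoring, and matplotlib 3.10.9 for the plots.

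The 29 gene lists were written before the data were examined, and 774 of their 856 distinct genes were measured. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists, with an estimated correlation and fry as alternatives, and their members were also adjusted over the list alone. In 20 simulated sets of 4 arrays without effects, the preset called 0 of 580 lists when genes were independent and 105 (18.1%) when list members shared a correlation of 0.2. An estimated correlation called 0 in both cases. "Rose" and "fell" are used of list members that passed when adjusted over the list alone, and of MIR210HG and NMRAL2P over all genes.

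The rule for named genes, fixed before the data were examined, took up to 10 rises and 10 falls among genes called over all genes whose EDHB arrays both lay beyond both untreated arrays, up to 4 called members of each list that passed or was named, and 24 fixed genes. It gave the 2 called genes and 0 list members. The members with the largest changes among those called over the list alone were named in addition, a choice made after the values were seen, as were the genes named from the intensity-trend fit and other list members given as examples. Of the fixed genes, CA9, FTH1, EGLN3 and CYP1A1 had no restored probe set with 1 gene and are not analysed here over both replicates.

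Alternatives fixed beforehand were a replicate block, leaving out each array, removing dim probe sets (mean log2 level not above the median of 4.54), the mean of all probe sets of a gene, every probe set tested on its own, centring arrays on their medians, cyclic loess, the intensity trend, robust eBayes, an adjusted p under 0.01, and the 2 other list tests. Added after seeing the data were the table as deposited and posterior minimums of 0.5 and 0.99. The intensity-trend fit under each other setting and the list members without each array or with the block were added then too.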

Results

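Gene expression was measured in KYSE170, a human cell line from an oesophageal squamous cell carcinoma, with oligonucleotide arrays that read most genes with several probe sets. Cultures were left untreated (2 arrays) or were given EDHB at 50 µg/ml for 12 h (2 arrays). EDHB is the ethyl ester of protocatechuic acid and inhibits prolyl hydroxylases, enzymes that need iron and 2-oxoglutarate and that mark the hypoxia-inducible factors for degradation. The comparison asked which genes differed after exposure to the compound. Median linear intensity lay between 23.3 and 23.5 on the 4 arrays. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure the spread between these arrays, and the number of arrays limits the precision.

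The replicate 2 columns of the deposited table did not stand in the same row order as the replicate 1 columns. Over rows as deposited, the log2 levels of the 2 EDHB arrays correlated across probe sets at only 0.418, whereas untreated and EDHB arrays of the same replicate number correlated at 0.996 and 0.995. Of the rows in running order, 98.2% had moved, by up to 79 rows. The order was restored for 54467 of 54613 probe sets from the levels of the untreated arrays. The EDHB arrays then correlated at 0.997. Their levels follow the untreated levels of the same replicate number, so even a wrong row of similar level would raise this value, and it is a weak check. All values of both groups below rest on this restored table. The log2 change within replicate 1 (EDHB 1 minus untreated 1) does not need the restoring, and is given beside that within replicate 2 for the main genes.

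**Figure D1:**
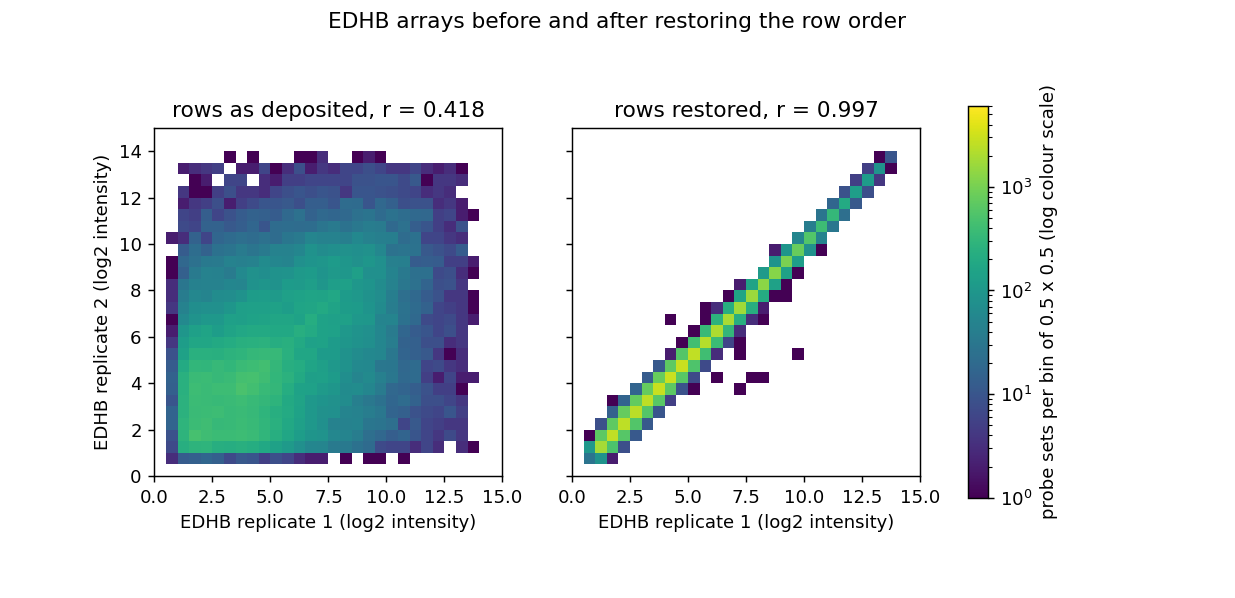
Log2 intensity of EDHB replicate 2 (y axis) against EDHB replicate 1 (x axis) for the probe sets, as counts per bin of 0.5 by 0.5 log2 units on a logarithmic colour scale, with the rows as deposited (left) and restored (right). The correlation across probe sets went from 0.418 to 0.997. EDHB levels follow the untreated levels of the same replicate number (0.996 and 0.995), so rows matched on untreated levels raise this value largely by construction.

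Among 19752 genes, 2 passed the threshold in limma with Benjamini-Hochberg adjustment, and both rose. MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210, rose from a log2 level of 2.89 ± 0.05 to 5.10 ± 0.06 (SD, n = 2 each; adjusted p = 0.0217). The untreated level lay below the median probe set (4.54) and was not shown to be above background, so the size of this change is uncertain. NMRAL2P, a pseudogene known as a target of NRF2, rose 3.73-fold, from 5.63 ± 0.09 to 7.53 ± 0.01 (SD, n = 2 each; adjusted p = 0.0260). The increases were 2.14 and 2.29 log2 units within replicates 1 and 2 for MIR210HG, and 1.83 and 1.97 for NMRAL2P. Each had 1 restored probe set, and both differences exceeded 2-fold. A further probe set of MIR210HG that was not restored in replicate 2 was higher by 2.01 within replicate 1. Neither gene was called with the replicate block or with a posterior minimum of 0.5. The count fell to 0 without any 1 of the 4 arrays, when 1 group was left with a lone sample assumed to vary like the others.

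The low count went with a crowd of genes just past the threshold. At an adjusted p under 0.1, 144 genes were called, 95 higher and 49 lower, and 3341 genes had an unadjusted p under 0.05 where 987.6 would be chance. With the intensity trend in limma's prior variance, an alternative fixed before the data were examined, 475 genes were called, 271 higher and 204 lower, of which 40 changed at least 2-fold (33 higher, 7 lower). This count too fell to 0 without any 1 of the 4 arrays, and to 0 with a replicate block. Both scalings moved the count of 2 from the fit without a trend. It became 44 (32 higher, 12 lower) after centring the arrays on their medians and 40 (30 higher, 10 lower) after cyclic loess. For the trend fit the same scalings gave 994 (582 higher, 412 lower) and 1007 (589 higher, 418 lower). In 26 genes the change reached 2-fold within both replicates, 20 higher and 6 lower, against 0 genes in which replicate 2 differed 2-fold from replicate 1 in both conditions (1 when paired across conditions). With untreated 2 and EDHB 1 set against untreated 1 and EDHB 2, the count was 2 within conditions and 1 within replicates. The restoring chose rows by the closeness of the untreated arrays, which works against such differences between replicate numbers. Of all genes, 45.8% had both EDHB arrays beyond both untreated arrays, where chance gives 33.3%.

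Many genes known to be induced by hypoxia rose. Of 37 measured members of the hypoxia list, which left out glycolysis, 23 rose and 1 fell when adjusted over the list alone, 13 did not pass, and 0 were called over all genes in limma, with 26 at an unadjusted p under 0.05. NDRG1, a stress-induced growth regulator, rose 4.91-fold, from a log2 level of 6.91 ± 0.18 to 9.21 ± 0.45 (SD, n = 2 each), by 2.10 and 2.49 within replicates 1 and 2. VEGFA, the angiogenic growth factor, rose 2.50-fold, from 8.08 ± 0.05 to 9.40 ± 0.15 (SD, n = 2 each). That is 1.32 log2 units on its brightest probe set, whereas its 3 other restored probe sets gave only 0.66 to 0.71. The mitophagy receptors BNIP3 and BNIP3L rose 2.20-fold and 2.53-fold, and DDIT4, an inhibitor of mTORC1 signalling, rose 2.53-fold. P4HA1, a subunit of collagen prolyl hydroxylase, rose by 0.90 ± 0.09 (SE) log2 units. Its other probe set gave 0.00, at levels of 1.14 to 1.48, below the median probe set and not shown to be above background. ADM, ANKRD37 and the lysyl hydroxylase PLOD2 rose by 0.84, 0.91 and 0.67. JMJD6, itself an oxygenase, fell by 0.48. Its median was 0.48 (0.39 and 0.48 within replicates 1 and 2), and camera with its preset correlation called the list higher (adjusted p = 1.19e-16). With an estimated correlation the call was lost (adjusted p = 0.378). That setting takes its p-values from 2 residual degrees of freedom, and it lost even G2 and mitosis, whose estimate of 0.016 lay near the preset 0.01. A loss there does not by itself show correlation among members. The estimate was 0.158 for the hypoxia list and ran from -0.033 to 0.659 over the 15 called lists. At a correlation of 0.2 the preset called 18.1% of simulated lists without effects, so preset p-values of the more correlated lists may be too small.

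Among the genes of oxygen sensing, EGLN1 rose 1.44-fold when adjusted over the hypoxia list, by 0.52 ± 0.09 (SE). EGLN1 is the main prolyl hydroxylase of HIF and a HIF target. Of its 3 other restored probe sets, 1 gave -0.004, at levels of 3.69 to 3.86, below the median probe set. Log2 changes were 0.01 ± 0.08 for HIF1A, 0.18 ± 0.08 for EPAS1, 0.15 ± 0.07 for ARNT and 0.00 ± 0.08 for the asparaginyl hydroxylase HIF1AN (SE, n = 2 and 2), and none passed. EGLN2 had mean levels of 3.88 and 3.78, below the median probe set, and no change is given. Of the other probe sets of ARNT, 1 of 6, below the median probe set, went the other way, as did 1 of 2 of HIF1AN. The 2 probe sets of EGLN3 were not restored in replicate 2, and within replicate 1 they were higher by 1.69 and 1.21, with no test. Across the 2-oxoglutarate dioxygenases, 7 of 47 measured members rose and 3 fell when adjusted over the list alone. P4HA1, PLOD2, EGLN1 and the histone demethylase KDM7A were among those that rose, and JMJD6, ALKBH2 and RIOX2 fell, with 1 of the 3 other probe sets of JMJD6 going the other way. That list as a whole did not pass (median 0.05, adjusted p = 0.0976 with camera, 0.494 with an estimated correlation).

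Few glucose uptake and glycolysis genes passed. Of 25 measured members, 3 rose when adjusted over the list alone and 22 did not pass. These were the neuronal-type enolase ENO2 (2.39-fold), the aldolase ALDOC (1.79-fold) and the glucose transporter SLC2A1 (1.56-fold). The median was 0.17 with 21 members above 0, and the camera adjusted p was 1.14e-05, against an adjusted p = 0.378 with an estimated correlation. Without EDHB replicate 2 or either untreated array, 1 member passed. Among genes of iron uptake, storage and regulation, 4 of 23 rose when adjusted over the list alone. These were the iron-responsive aconitase ACO1 (0.46 log2 units), the haem oxygenase HMOX1 (0.41), the ferric reductase CYBRD1, which went from 4.16, below the median probe set, to 5.50, and ceruloplasmin CP, whose levels of 2.70 and 3.14 both lay below it and of whose 3 other probe sets 1 went the other way. The transferrin receptor TFRC changed by 0.11 ± 0.07 (SE) and did not pass, and 1 of its 4 other probe sets gave -0.07. The iron list was not called by camera (median 0.03, adjusted p = 0.0721, and 0.381 with an estimated correlation).

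Most genes of G2 and mitosis fell. Of 40 measured members, 33 fell and 0 rose when adjusted over the list alone, and 7 did not pass. CDC20, the activator of the anaphase-promoting complex, fell by 1.29 on the log2 scale, from 11.23 ± 0.08 to 9.94 ± 0.01 (SD, n = 2 each). The kinesin KIF20A fell by 1.17, and the mitotic kinases PLK1 and AURKA fell by 1.13 and 1.07. For AURKA the change was -1.07 within each replicate. Cyclin B1 (CCNB1) fell by 0.97 and the kinetochore motor CENPE fell by 0.94. The proliferation marker MKI67 changed by -0.29 ± 0.15 (SE) and did not pass. Over the list the median was -0.46 (-0.47 and -0.45 within replicates 1 and 2), with a camera adjusted p of 9.33e-25. With an estimated correlation the adjusted p = 0.296, and 21 members passed without EDHB replicate 2.

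Of 47 measured DNA replication and S phase genes, 1 rose when adjusted over the list alone, the cyclin CCNE2 (1.76-fold), 0 fell and 46 did not pass, with 13 at an unadjusted p under 0.05 in limma. The median was 0.04, and the list was called higher by camera at an adjusted p of 0.0492, which rose to 0.429 without EDHB replicate 1 and 0.338 without untreated replicate 2, to 0.101 with dim probe sets removed and to 0.0517 with arrays centred on their medians. The adjusted p = 0.646 with an estimated correlation. CDKN1A, the inhibitor of cyclin-dependent kinases known as p21, rose 1.96-fold, from 7.92 ± 0.09 to 8.89 ± 0.06 (SD, n = 2 each), when adjusted over the p53 target list. In that list 4 of 24 members rose and 1, the nuclease AEN, fell (list median 0.08, camera adjusted p = 0.0700, and 0.381 with an estimated correlation). CCND1 changed by -0.42 ± 0.09 and MYC by 0.01 ± 0.20 (SE), and neither passed over all genes.

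Most genes of ribosome biogenesis and the nucleolus also fell. Of 30 measured members, 25 fell when adjusted over the list alone and 5 did not pass. UTP15, a component of the small-subunit processome, fell by 0.79, the ribosome assembly factors NOP16 and RRS1 fell by 0.71 and 0.67, and WDR74 fell by 0.66. Of the other probe sets, 1 of 3 of NOP16 and 1 of 2 of WDR74 went slightly the other way. That of WDR74 lay below the median probe set. The second-largest subunit of RNA polymerase I, POLR1B, fell by 0.64. This list had a median of -0.40, with -0.31 within replicate 1 and -0.51 within replicate 2, and the camera adjusted p was 2.01e-17. With an estimated correlation the adjusted p = 0.381. Without untreated replicate 1, untreated replicate 2 or EDHB replicate 2, 0 members passed. The cytosolic ribosomal proteins themselves had a median change of 0.02 over 26 members and 0 calls over the list alone, with 0 members at an unadjusted p under 0.05 in limma.

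Targets of ATF4, the transcription factor of the amino acid and integrated stress response, were among the genes that rose. Of 30 measured members, 19 rose when adjusted over the list alone and 11 did not pass. Among the 11 were members with a further probe set, not restored in replicate 2, that was higher by 1.04 or 1.08 within replicate 1. GDF15, a stress-induced cytokine, rose 3.31-fold, from 6.09 ± 0.52 to 7.82 ± 0.05 (SD, n = 2 each). Its 2 other probe sets, both below the median probe set, changed by -0.05 and 0.69. The amino acid transporter SLC1A4 rose 2.78-fold and NUPR1 2.77-fold. The glutathione-degrading enzyme CHAC1 went from 4.40, below the median probe set, to 5.81. Other members that rose were CTH of the transsulfuration pathway (1.38 log2 units), ATF3 (1.05), PHGDH of serine synthesis (0.74) and ATF4 itself (0.58). The list median was 0.42, with a camera adjusted p of 1.58e-14 and an adjusted p = 0.378 with an estimated correlation. Without untreated replicate 2, EDHB replicate 1 or EDHB replicate 2, 12, 2 and 3 members passed.

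Of 31 measured genes of the NRF2 antioxidant response, 11 rose when adjusted over the list alone and 20 did not pass. The aldo-keto reductases AKR1C3, AKR1C2 and AKR1C1, which are close in sequence and can share probes, rose 2.58-fold, 2.06-fold and 1.99-fold. GCLC, the catalytic subunit of glutamate-cysteine ligase, rose 2.09-fold, and its partner GCLM rose by 0.50 log2 units. HMOX1 rose by 0.41, and SLC7A11, which the ATF4 list also holds, rose by 0.74. SQSTM1 changed by 0.26 ± 0.12 (SE) and did not pass over all genes. For this list the median was 0.23, with a camera adjusted p of 1.29e-09 and an adjusted p = 0.378 with an estimated correlation. Without untreated replicate 2, EDHB replicate 1 or EDHB replicate 2, 4, 3 and 3 members passed.

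In the list of endoplasmic reticulum chaperones and the unfolded protein response, 5 of 25 members rose when adjusted over the list alone, led by HERPUD1 (1.95-fold), DNAJB9 (1.58-fold), XBP1 (1.47-fold) and DNAJC3 (1.35-fold). Its median was 0.16, with a camera adjusted p of 3.97e-06 and an adjusted p = 0.378 with an estimated correlation. Of 38 autophagy genes 10 rose, among them BNIP3L and BNIP3, which the hypoxia list also holds, the phosphoinositide-binding protein WIPI1 (1.73-fold), the initiating kinase ULK1 (1.71-fold) and MAP1LC3B (1.41-fold). The autophagy median was 0.16, with adjusted p values of 4.00e-06 with the preset and 0.378 with an estimated correlation. In the BCL2 family and cell death list 6 of 27 rose, including BNIP3L, BNIP3, BMF (1.45-fold) and APAF1 (1.42-fold), and BIRC5, a mitotic gene of the G2 list, fell (median 0.12, camera adjusted p = 0.00290, and 0.378 with an estimated correlation). Of 25 lysosomal genes 1 rose, the cholesterol exporter NPC1 (1.53-fold), with a list median of 0.11 (camera adjusted p = 5.74e-04, and 0.494 with an estimated correlation). Without any 1 array at most 2 members of the reticulum list passed, 1 of the autophagy list, 1 of the cell death list and 0 of the lysosome list.

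Among 18 measured genes of cholesterol synthesis and uptake, 4 rose when adjusted over the list alone. INSIG1, the sterol-sensing retention protein, rose 2.57-fold, and the synthesis enzymes MSMO1, IDI1 and HMGCS1 rose 1.69-fold, 1.60-fold and 1.32-fold, with 2 of the 3 other probe sets of IDI1 going the other way. The list median was 0.12 (camera adjusted p = 2.29e-04, and 0.420 with an estimated correlation), and 1 member passed without untreated replicate 2 or EDHB replicate 2. Of 25 interferon-stimulated genes 5 rose, among them OAS1 (1.44-fold), OAS3 (1.41-fold) and PSMB9 (1.33-fold). Another of the 5, CXCL11, had mean log2 levels of 2.08 and 2.50, below the median probe set and not shown to be above background, and no fold is given. That list had a median of 0.19 (camera adjusted p = 5.74e-04, and 0.393 with an estimated correlation), and 0 members passed without any 1 array. The 11 aryl hydrocarbon receptor targets had a median of 0.17 and 0 members called over the list alone in limma, with 3 at an unadjusted p under 0.05. That list passed camera (adjusted p = 0.0125), but not with an estimated correlation (adjusted p = 0.378) or without EDHB replicate 1 (0.113). CYP1A1 was not restored in replicate 2 (posterior 0.944) and is not analysed here in both replicates. Within replicate 1 it was higher by 0.77, with no test.

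Of 27 measured immediate early and ERK feedback genes, 2 rose when adjusted over the list alone, ETV5 (1.74-fold) and FOSL2 (1.39-fold). Of the 4 other probe sets of ETV5, 1, below the median probe set, went the other way. The list median was 0.28 within replicate 1 and 0.00 within replicate 2. Camera called the list higher (adjusted p = 0.00169), and the call was lost without EDHB replicate 1 (adjusted p = 0.663) and with an estimated correlation (adjusted p = 0.592). With EDHB replicate 2 left out, 7 members passed.

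The remaining 11 lists were not called by camera. The medians were -0.10 for metallothioneins and zinc transport (adjusted p = 0.0699), -0.09 for heat shock (0.0721), 0.06 for basal squamous epithelium (0.134) and -0.09 for iron-sulfur cluster and haem synthesis (0.180). Markers of fibroblasts, endothelium and leukocytes, which a pure epithelial line should hardly express, had a mean log2 level of 3.78 and a median change of -0.07 (adjusted p = 0.496). Squamous keratinocyte differentiation (0.02, adjusted p = 0.681), mesenchymal genes (-0.05, 0.712) and oxidative phosphorylation (0.01, 0.880) showed no shift by this test. Inflammatory NF-kB targets (-0.02, 0.858), collagens (0.03, 0.985) and the cytosolic ribosomal proteins (0.02, 0.553) did not either. For the NF-kB list the median lay below 0 while the mean and camera put the list above 0. Its median was 0.20 within replicate 1 and -0.24 within replicate 2, so the replicates went opposite ways and the list was not flat within either. Within that list CXCL1, a neutrophil-attracting chemokine, rose 2.12-fold when adjusted over the list alone.

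**Figure D2:**
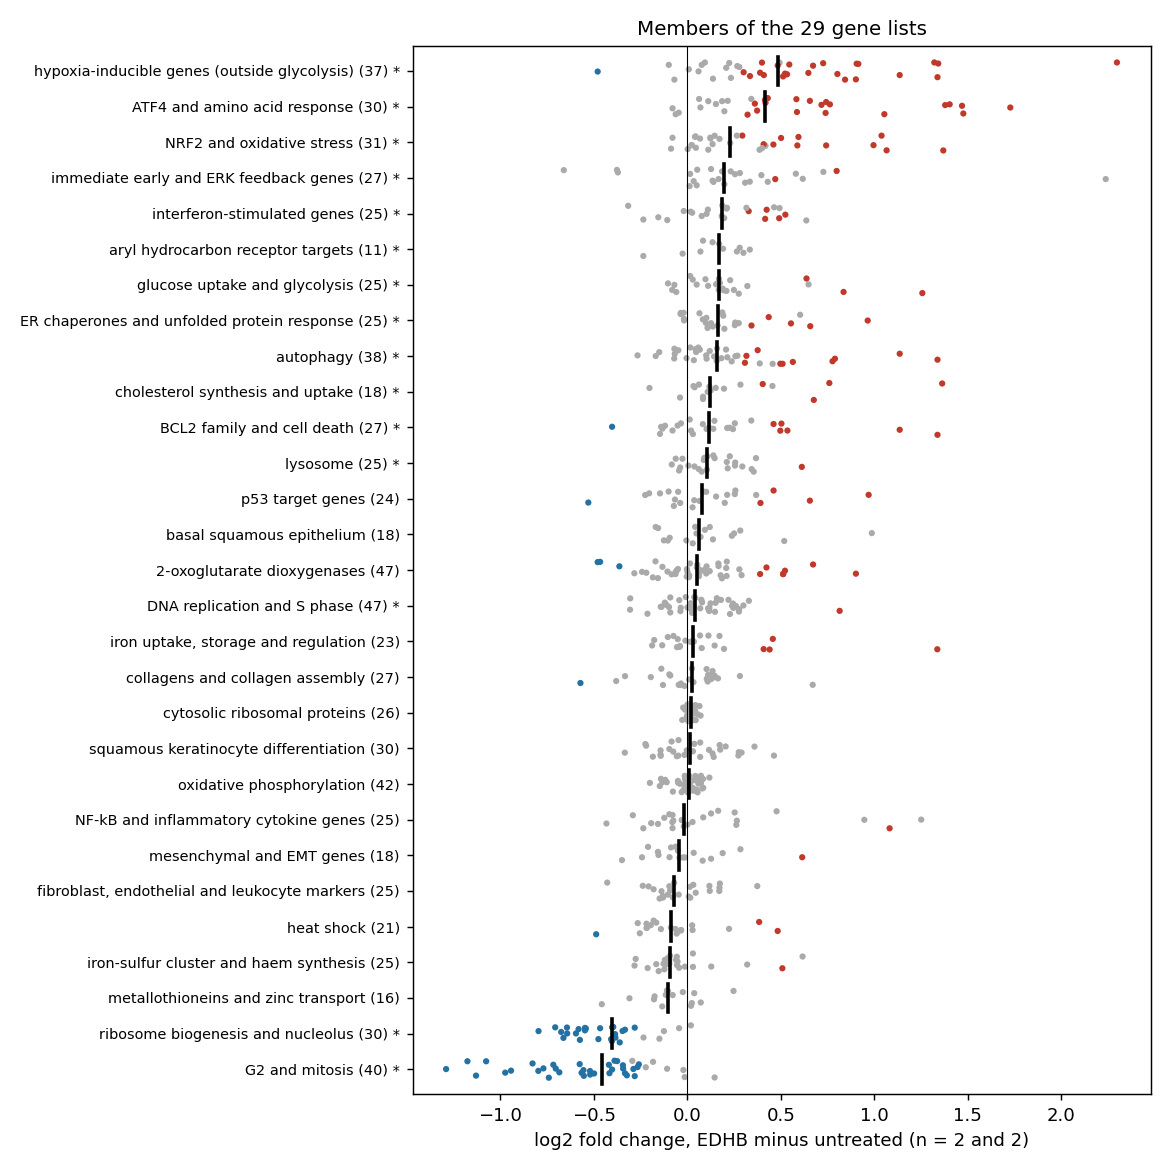
Log2 fold change of each measured member (points, x axis, EDHB minus untreated, n = 2 and 2) of the 29 gene lists (y axis, number measured in parentheses), with list medians as black bars. Red and blue points rose or fell in limma at an adjusted p under 0.05 over the list alone, grey points did not pass, and asterisks mark the 15 lists called by camera with its preset correlation, of which 0 were called with an estimated correlation. The medians run from -0.46 for G2 and mitosis to 0.48 for the hypoxia-inducible genes.

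**Figure D3:**
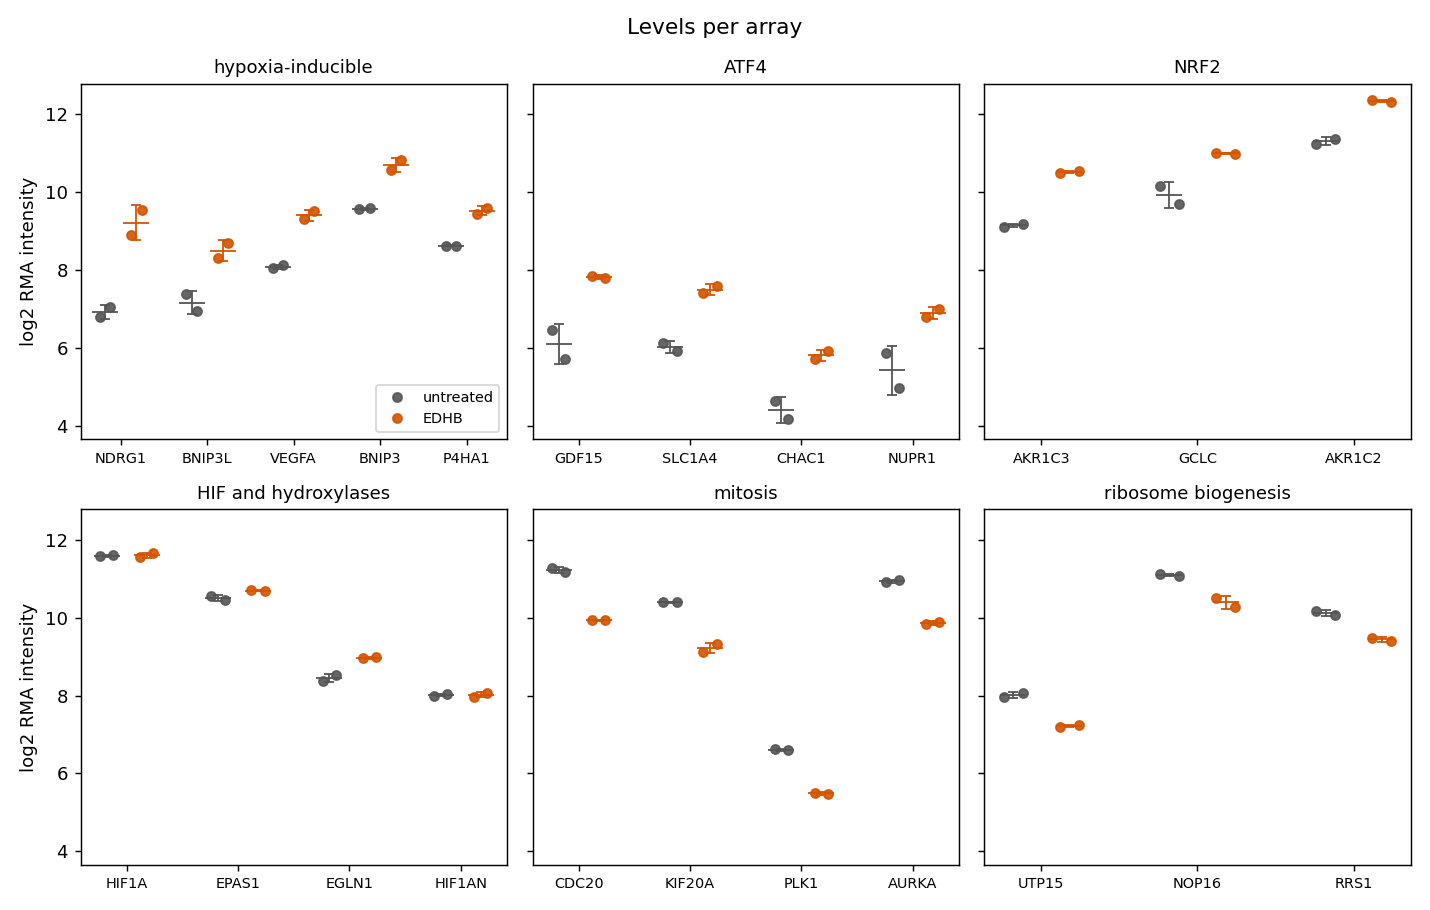
Log2 RMA intensity (y axis) on each array (points) for named genes of 6 groups, with the mean and SD of each group of 2 arrays, untreated in grey and EDHB in orange. Both EDHB arrays lie above both untreated arrays for the hypoxia-inducible, ATF4 and NRF2 genes shown and below them for the mitosis and ribosome biogenesis genes, whereas HIF1A and HIF1AN overlap.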

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

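The tests of the intensity-trend fit under other settings, of the table as deposited, of other posterior minimums and of list members without an array were chosen after seeing the data. Against 2 called genes, 593 (359 higher, 234 lower) were called with dim probe sets removed. That setting tested 12400 genes and took the prior variance from those genes alone. In the main fit only 144 genes had an adjusted p under 0.1, so fewer tests alone cannot give 593. There were 51 with the mean of probe sets, 44 with arrays centred on their medians, 40 with cyclic loess and 475 with the intensity trend. The count was 0 with the replicate block, with every probe set tested on its own, at an adjusted p under 0.01, with a posterior minimum of 0.5 and with the rows as deposited, and 0 to 0 over the fits without 1 array, where fewer samples entered the test. It was 2 with robust eBayes and with a posterior minimum of 0.99. For genes changed at least 2-fold, against 2, the same settings gave 38, 22, 25, 24 and 40, then 0 with the block, every probe set, the stricter threshold, the lower posterior minimum, the rows as deposited and each left-out array. The 475 genes of the trend fit became 1200 with dim probe sets removed, 994 after centring, 1007 after cyclic loess, which included all 475, 930 with robust eBayes, 82 over single probe sets and 30 at an adjusted p under 0.01. It became 0 with the replicate block, with the rows as deposited and over the fits without 1 array. What caused these changes in count was not tested. The largest shift of an array's median under centring was 0.009 log2 units. In the remaining 2 ways of splitting the 4 arrays into pairs, 0 genes were called by either fit, but 3 splits are too few for a share under 0.05. Those splits put 1 untreated and 1 EDHB array on each side, so the treatment difference enters the residual spread. The restoring also matched the untreated arrays in level. Both work against calls, so the 0 decides nothing.

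The lists called numbered 15 in the main test, 14 to 17 without 1 array, 16 with the replicate block, and 14 to 17 under the other settings of levels and posterior minimums. They numbered 0 with an estimated correlation, which tests on 2 residual degrees of freedom and so lost even G2 and mitosis (estimate 0.016, near the preset 0.01), 3 by fry (BCL2 family, G2 and mitosis, and iron) and 12 with the rows as deposited, where replicate 1 still stood right. The lists of hypoxia, ATF4, NRF2, G2 and mitosis, and ribosome biogenesis kept their call and direction under all 11 settings other than fry, the estimated correlation and the deposited rows. Of the 15 lists, 3 lost it under at least 1 of those 11. Only the aryl hydrocarbon receptor targets changed direction, to a median of -0.019 with the rows as deposited. The replicate numbers share no stated origin, although the inferred layout sorted same-numbered arrays as pairs. The deviations of same-numbered arrays from their group means correlated across genes at 0.09. The restoring matched the untreated arrays in level and so shrinks such deviations, so this value cannot decide whether the arrays were paired. With the replicate block, 33 G2 and mitosis genes, 27 hypoxia genes, 17 ATF4 genes and 12 NRF2 genes were called over the list alone, while autophagy went from 10 to 4 and interferon-stimulated genes from 5 to 0. Signal over background is not part of the table, so dim genes rest on levels that no detection call backs.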

Other observations

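The tests of explanations below, on separate probe sets, immediate early genes, equally bright genes, S phase genes and left-out arrays, were each written after results bearing on them were seen. Several of the genes that changed most stood outside the lists. They are named from the intensity-trend fit, after their values were seen, and none but MIR210HG and NMRAL2P passed the main test over all genes. That fit called 0 genes without any 1 of the arrays and 0 with the replicate block, so its adjusted p-values hold for the 4 arrays together alone. CCNG2, an atypical cyclin, was 2.96-fold higher (1.35 and 1.78 log2 units within replicates 1 and 2, trend adjusted p = 0.0136). Of its 2 other restored probe sets, 1, below the median probe set, went the other way. A pair of its probe sets not restored in replicate 2 was higher by 1.52 and 1.49 within replicate 1. The chloride channel protein CLIC4 was 2.74-fold higher (trend adjusted p = 0.00831), and GRHL3, a transcription factor of epidermal differentiation, was 2.71-fold higher (1.69 and 1.18, trend adjusted p = 0.0206). The nuclear receptor coactivator PNRC1 was 2.46-fold higher. MAB21L3 went from 2.79 to 4.20, both below the median probe set and not shown to be above background. On the lower side, TNFAIP8L1 changed by -1.24, the mitotic spindle gene PSRC1 by -1.16 (-1.12 and -1.20 within replicates 1 and 2) and the interleukin receptor IL7R by -0.99 (trend adjusted p = 0.0194, 0.00831 and 0.0362). ANKRD1, a target of YAP, went from 4.23 to 3.17, both below the median probe set and not shown to be above background.

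Some immediate early and inflammatory genes were higher with EDHB within replicate 1 alone. EGR1 was 4.72 log2 units above untreated within replicate 1 and changed by -0.25 within replicate 2, CXCL8 by 2.29 and -0.40, and PTGS2 by 1.43 and -0.48. CCN2 was 2.27 higher within replicate 1 and lay at 3.59 on EDHB replicate 2, below the median probe set and not shown to be above background. FOS reached 5.46 on EDHB replicate 1 and lay below the median probe set on the other 3 arrays. PTGS2 lay at 6.46 and 7.77 on untreated replicates 1 and 2 and at 7.89 and 7.30 on EDHB replicates 1 and 2, so the untreated arrays differed too, as they did for CXCL8 (7.20 and 8.33). A wrong row in replicate 2 could give such a gap. The 2 probe sets of CXCL8, in rows far apart, agreed in replicate 2 (untreated 2 minus untreated 1 was 1.13 and 1.17), and so did those of PTGS2 (1.32 and 1.35). Among pairs of other rows near them, no farther from untreated replicate 1 in level, 0.271% and 1.303% agreed as closely, which argues against wrong rows for these genes. For EGR1 33.3% of such pairs did, since its EDHB replicate 2 levels lay near the untreated ones, as those of rows chosen by untreated level would. FOS and CCN2 have 1 restored probe set each. A wrong row stays open for these 3, although all were restored at a posterior near 1. Over the immediate early list fixed beforehand, EDHB replicate 1 exceeded EDHB replicate 2 by a median of 0.327, against -0.04 between the untreated arrays, and different handling of that culture cannot be told apart from a different response to EDHB in it, since each group has 1 array per replicate number.

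The fall of G2 and mitosis genes stood beside S phase genes that did not fall. A difference between arrays that depends on brightness would lower other genes of the same level alike. The median of members of other lists within 0.5 log2 units of each gene was 0.073, which lay 0.53 above that of G2 and mitosis. Over all genes the median was -0.0014, and lists called higher were among those other lists, so they may widen the gap slightly. The gap exceeded the SD of 0.361 among those members, which argues against brightness as the cause of the whole fall. Cyclic loess moved no value by more than 0.028 and decides nothing on this. Fewer cycling cells, with all phases lowered alike, would lower S phase genes by about as much if both lists depended equally on cycling cells. Whether they do was not tested. The S phase median lay 0.501 above that of G2 and mitosis, more than the SD of 0.189 among its members, a spread between genes. This speaks only to an equal loss of all phases, and only if both lists depend equally on cycling cells. Cells held before G2 are not covered, since S phase genes need not fall in them, and cell cycle phase was not measured. A difference in culture density between the groups stays open, since it would go with the treatment and no label gives it.

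For the ribosome biogenesis genes the median was at or below -0.348 without any 1 array, which argues against 1 array as the source of the fall. Equally bright members of other lists, compared in the same way, had a median of 0.069, which lay 0.473 above that of this list. The SD among them was 0.373, which argues against brightness as the cause of the whole fall. The margin is narrow, since the list median of -0.404 alone lies only a little beyond that SD. As the ribosome biogenesis genes rose and fell together between arrays (estimated correlation 0.659), their number may overstate the evidence. An effect of EDHB and a difference between cultures that goes with it stay open.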
